A study of Homo sapiens with 4 samples.

How the data were processed

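RNA of HEK293 cells, an established human embryonic kidney line, was sequenced from 2 fractions of the same cytosolic extract: the whole cytoplasm and the polyribosomes, the part of the extract in which an mRNA carries several ribosomes. Per the labels' protocols, the cells were starved of glutamine for 12 h and then cultured in complete medium for 7 h, 10% of a detergent extract was kept for cytoplasmic RNA, the rest was spun through sucrose gradients of 15 to 45% at 100000 g, and libraries were made from polyadenylated RNA with an Illumina kit. The 4 libraries analysed are the DMSO controls, with 2 replicates per fraction. Rapamycin libraries were not analysed here, and the 4 columns of per-sample values that belong to them in the table of changed events were not used.

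The submitters' processing notes name TopHat2 2.0.4, Bowtie2 2.0.0, TopHat, SAMtools and the build hg19. Their roles and the settings of the isoform estimate are not given in the sources used here. The deposited values are fractions made by the authors with MISO, a Bayesian estimator of isoform use: for each alternative event of each library the share Psi of the first isoform, from 0 to 1, with its 95% interval. The authors also deposited a Bayes factor per event and replicate, a ratio of the evidence for a difference between polyribosomes and cytoplasm to the evidence for none, and the reads that fit each isoform. Psi is a share within 1 library, so no scaling between libraries enters it, and it says nothing of the gene's total level.

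The column headings of the replicate tables are shifted. The column headed as the lower bound holds Psi, the column headed as the upper bound holds the lower bound, and the column headed Psi holds the upper bound. This was checked in every row by the order of the values, and against the authors' table of changed events for the 598 events the tables share. Assigned-read cells that spreadsheet software had turned into clock times were restored from the total of fitting reads, in 35, 34, 45 and 31 events of cytoplasm 1, polyribosome 1, cytoplasm 2 and polyribosome 2, and 0 stayed unresolved.

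The replicate tables hold 1954 events in 1432 named genes, and they are a selection that the authors made on these same libraries. The 597 events they marked different have Bayes factors of at least 5.02 and Psi differences of at least 0.11 in the same direction in both replicates, and the 1357 marked not different have Bayes factors of at most 0.99 in both. Events between these limits were not analysed here. Call rates are therefore rates within this selection, and the calls are no independent evidence beside the authors' marks.

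Psi was held between 0.01 and 0.99 and put on the logit scale to base 2. Events with a mean 95% interval width of at most 0.4 over the 4 libraries were tested, which kept 1533 events and left out 421. limma 3.58.1 in R 4.3.3 fitted polyribosome minus cytoplasm with the replicate number as a block, with trend and robust settings, and p-values were adjusted by the Benjamini-Hochberg method over the tested events with a threshold of 0.05. These are the changed events of every later comparison. The block follows from the protocol, in which both fractions of a number come from 1 extract. The deviations of same-numbered libraries from their group means had a correlation of 0.37 across the tested events. It was 0.155 in events marked different and 0.437 in those marked not different. The latter were selected for like Psi in both fractions of each replicate, which favours such a correlation. The value is therefore no separate evidence of pairing. The fit leaves 1 residual degree of freedom per event and borrows the spread of the other events, which gave a median of 134.8 total degrees of freedom, against 7.67 with Psi spread at random within its rounding step and 8.42 with weights by interval width. The size of a small p-value therefore depends on this borrowing and is no measure of the size of a change. Data were simulated from the mean logit of each of the 1533 events, with 200 events changed. The noise was independent and normal, with the spread that limma itself had estimated. The fit recovered 1.49% of changes of 0.5 on the logit scale, 23.9% of changes of 1 and 90.9% of changes of 2. There were 4.94% false calls and 0 wrong directions. Such noise follows the model's own assumptions, so these values do not show the false call rate in the selected real events. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

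A rule without a p-value was applied beside the test: a Bayes factor of at least 10 and a Psi difference of at least 0.1 in the same direction in both replicates. Shares of events have exact Clopper-Pearson 95% intervals, which cover counting error only. The direction of the minor isoform, the one below 0.5 in cytoplasm, was also tested by 100000 permutations of the signs over events. Event classes and gene lists were compared with all other tested events by 2-sided Fisher exact tests, and directions by 2-sided exact binomial tests, each adjusted over the classes or lists. Further direction tests, on subsets of events, were adjusted together over 26 tests. The skipped exons whose length is a multiple of 3 were compared with the rest by a permutation test with 100000 draws. Events are not independent replicates, since several events of a gene can share reads. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A Cochran-Mantel-Haenszel test on assigned reads, run as an alternative, recovered 92.5% of 200 simulated changes of 2 on the log2 odds scale, with 2.63% false calls. It treats reads as independent and so covers counting error, not the spread between libraries.

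Genes are named by a rule fixed before the data were examined, as were the main test of each comparison, the gene lists and the alternatives, except those that the closing section names as added later. Direction tests on subsets of events were chosen with the files at hand. Among changed events with the same direction in both replicates it takes the 12 largest rises and the 12 largest falls of Psi, 1 event per gene, and the changed events of SR proteins, translation factors and ribosomal proteins, at most 8 per list. Members of other lists, and exceptions to a direction, are named after their values were seen. Coordinates are those of the files, in hg19. Gene names are the authors'. The annotation at hand is of another build, so no position was taken from it, and it served only to look up the strand and chromosome of each named gene: 96.8% of the tested events have a gene name found there, 64 lie on another strand or chromosome than the gene they are named for, and 17 span more than 1 Mb. Alternatives changed the block, the bounds and scale of Psi, the width filter, weights, the libraries used, the test, the threshold, and the naming of the minor isoform.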

Results

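Frac-seq compares the isoforms of an mRNA that sit on polyribosomes with those in the whole cytoplasm, and the series asks which isoforms are preferred there. Cytoplasmic and polyribosomal RNA of control HEK293 cells was sequenced in 2 replicates each. Summed over the 1954 events, 1023953 reads of cytoplasm 1 and 1397286 of cytoplasm 2 fitted an isoform, with medians of 213 and 300.5 reads per event. The polyribosome libraries were shallower, with 520267 reads in replicate 1 and 549647 in replicate 2, and medians of 101 and 98 reads per event. The median 95% interval of Psi was accordingly 0.25 and 0.21 wide in the cytoplasm libraries and 0.31 wide in both polyribosome libraries.

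Isoform shares differed between polyribosomes and cytoplasm in genes of many kinds. The extended 3' UTR of IGFBP7, a secreted protein that binds insulin-like growth factors, made up a Psi of 0.93 in both cytoplasm libraries and 0.155 ± 0.0495 (SD, n = 2) in polyribosomes. In the opposite direction, an exon of BOD1L1, a protein that protects stalled replication forks, rose from 0.105 ± 0.0212 to 0.740 ± 0.113 (SD, n = 2). In limma, 567 of 1533 tested events in 372 genes differed, with Psi higher in polyribosomes in 257 and lower in 310. The median size of a changed event's difference was 0.265, with quartiles of 0.195 and 0.345, and the replicates' differences for the same event lay a median of 0.06 apart.

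Among the 12 largest rises, 7 were alternative last exons. The upstream last exon of RBBP6, a ubiquitin ligase that also takes part in mRNA 3' end formation, lies on chromosome 16 from 24560266 to 24560722. Its Psi was 0.150 ± 0.0141 in cytoplasm and 0.76 in both polyribosome libraries (SD, n = 2; adjusted p = 3.13e-16). The upstream last exons of CNTLN, a centrosomal protein, and GREB1, an oestrogen-induced gene, rose by 0.510 and 0.465, and that of the liver glycogen phosphorylase PYGL by 0.445. BRWD1, which carries bromodomains, rose from 0.495 ± 0.00707 to 0.935 ± 0.0495, and MLLT10, a cofactor of histone methylation, from 0.190 ± 0.0424 to 0.625 ± 0.106 (SD, n = 2). The last exon event named for LPCAT1, a lysophospholipid acyltransferase, rose by 0.615, but it lies on the other strand from that gene and its regions span 69338779 bases, so the gene name is uncertain. The remaining rises were the BOD1L1 exon on chromosome 4 from 13625014 to 13627936, a coding exon of WDR6 of 214 bases (by 0.505), the longer 5' splice site form of the Fanconi anaemia gene FANCA (by 0.470), the downstream first exon of C8orf76 (by 0.510), and a 5' UTR splice site form of UBA1, the ubiquitin-activating enzyme (by 0.435). The adjusted p of these 12 events ranged from 1.52e-18 for BOD1L1 to 5.05e-08 for UBA1. Their fitting reads in the thinnest library ranged from 25 in C8orf76 and GREB1 to 651 in BRWD1, with 27 in RBBP6 and 31 in BOD1L1.

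Among the 12 largest falls, 6 were skipped exons. A 5' UTR exon of GABPA, an ETS-family transcription factor, on chromosome 21 from 27113872 to 27113986, fell from 0.970 ± 0.0141 to 0.235 ± 0.106 (SD, n = 2; adjusted p = 1.26e-19). KCTD7, EMC1, a subunit of the endoplasmic reticulum membrane complex, PCGF5, a Polycomb group protein, and NDUFV3, a subunit of respiratory complex I, lost exons in polyribosomes with Psi differences of -0.665, -0.605, -0.555 and -0.535. The exon named for FTSJD2, an mRNA cap methyltransferase, had a difference of -0.615 but lies on the other strand from that gene. The longer 5' splice site form of the RNA helicase MOV10, in coding sequence on chromosome 1, fell from 0.975 ± 0.00707 to 0.355 ± 0.0778, and a 3' splice site form of the laminin gene LAMA4 from 0.975 ± 0.00707 to 0.395 ± 0.233 (SD, n = 2). IGFBP7, whose tandem UTR event spans chromosome 4 from 57896941 to 57897481, had the largest difference of all, at -0.775 (adjusted p = 2.14e-26). The others were the upstream last exon of ZNF33B (-0.560), the downstream first exon of the demethylase-family gene JMJD1C (-0.535) and a first exon named for the helicase SKIV2L (-0.540), again on the other strand from the gene. The spread between polyribosome replicates was large in some of these events, with 0.20 and 0.53 in PCGF5.

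**Figure D1:**
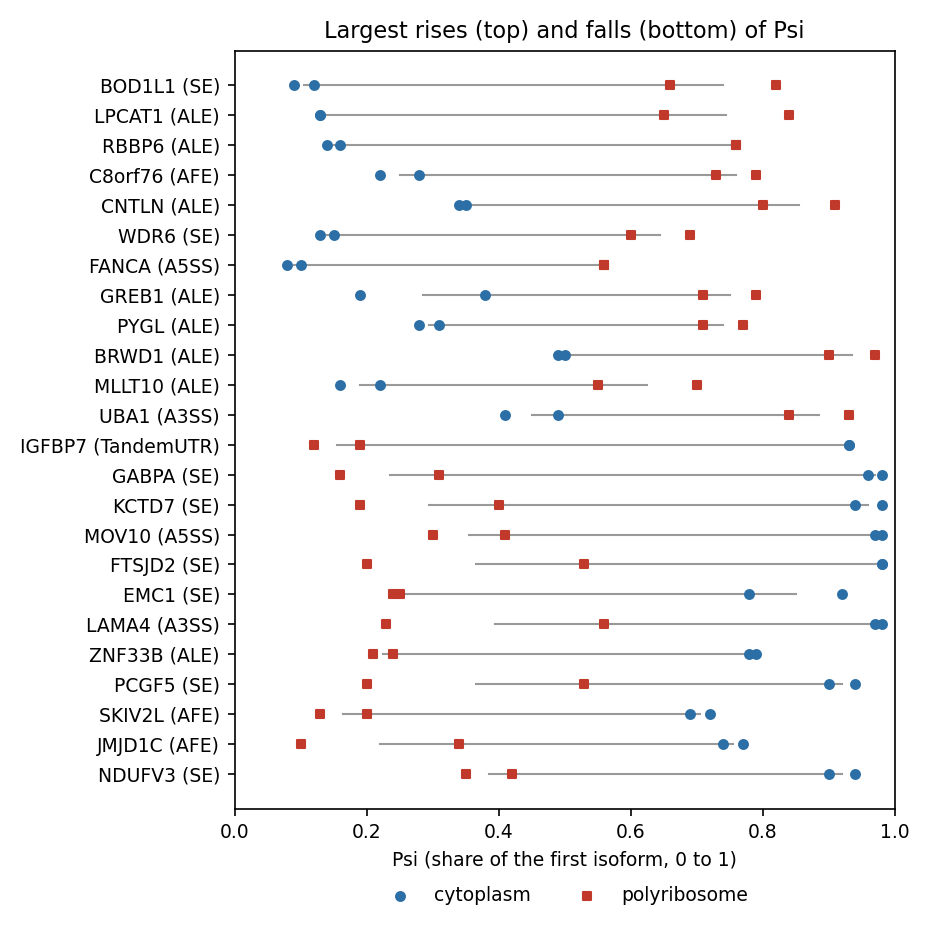
Psi (0 to 1, x axis) of the 12 largest rises and 12 largest falls, 1 row per gene with the event class in brackets (SE skipped exon, ALE and AFE alternative last and first exon, A5SS and A3SS alternative 5' and 3' splice site), with 1 circle per cytoplasm library, 1 square per polyribosome library and a line between the means. In every row the 2 polyribosome values lie on the same side of both cytoplasm values, as in IGFBP7 with 0.93 in cytoplasm.

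With any 1 library left out no block can be fitted, and the spread comes only from the 2 libraries of the other fraction. Psi deposited to 2 decimals then leaves 77 to 79 events with no residual at all, and limma called 0 events (420 to 480 at an unadjusted p under 0.05). With Psi spread at random within its rounding step it called 278 to 382. Very small p-values of single events rest on the spread borrowed from other events: with all 4 libraries and Psi spread at random, the adjusted p of IGFBP7 was 6.05e-04 and that of BOD1L1 0.00110, and with weights by interval width 1.25e-04 and 0.00346. With 1 event per gene, 340 of 1114 tested events differed.

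The Bayes factor rule gave a similar count, with 517 events past it in both replicates, of which 237 were higher and 280 lower in polyribosomes. This is no separate support, since the rule can only pass events that the authors marked different by the same measures. Of the 567 limma calls, 558 carry that mark. Of the 517, 486 were among the 567 that limma called, BOD1L1, RBBP6, IGFBP7 and GABPA included. UBA1 and LAMA4 did not pass the rule, with Bayes factors of 5.29 and 8.59 in replicate 2. Nor did some events named below, among them 5' UTR splice site forms of EEF1D (6.23 in replicate 1) and PNISR (6.67 and 5.46). With a Psi difference of at least 0.2, 312 passed. Across the tested events the Psi differences of replicates 1 and 2 had a Pearson correlation of 0.81 and a Spearman correlation of 0.69, with the same sign in 62.9%. This agreement sat in the events the authors marked different (0.96), which their selection holds to the same direction in both replicates. In those they marked not different the correlation was -0.12, and there 39.6% had the same sign. The 0.81 therefore depends on that selection and does not measure how well differences repeat. Correlations here are across events, which are not independent replicates.

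**Figure D2:**
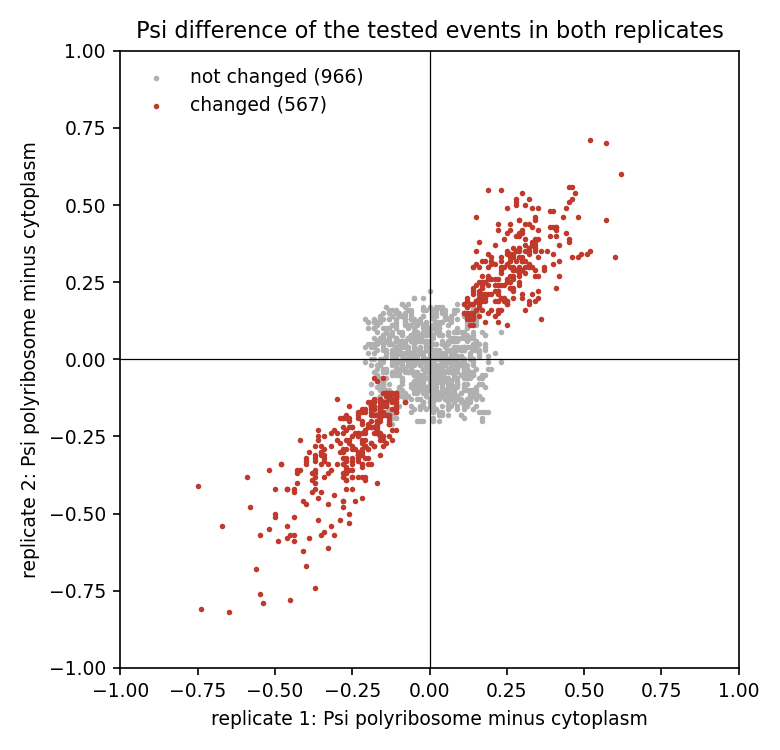
Psi difference, polyribosome minus cytoplasm, of 1533 tested events in replicate 1 (x axis) and replicate 2 (y axis), with red points for the 567 changed events and grey points for the rest. The changed events lie toward the lower left and upper right and the others around 0.

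Whether polyribosomes prefer some kinds of event was asked by class. Call rates by class are rates within the authors' selection, which leaves out events between their limits, and need not hold among all events. Overlapping events of a gene count separately in these rates. Alternative last exons changed most often, in 236 of 332 tested events (71.1%; odds ratio 6.46, Fisher adjusted p = 1.20e-45), and mostly toward the upstream exon, as in RBBP6, CNTLN and PNISR. The upstream last exon, whose use gives an mRNA that ends earlier in the gene, rose in 173 of 236 events (73.3%; 95% interval 67.2 to 78.8) and, with 1 event per gene, in 124 of 167. It rose in 125 of 147 events in which the upstream region was the shorter (85.0%), as in RBBP6, and in 42 of 81 in which it was the longer (51.9%; exact binomial adjusted p = 0.824). Its median Psi over the 236 events was 0.388 in cytoplasm and 0.568 in polyribosomes. ZNF33B and ATRX, a chromatin remodeller, were among the 63 events in which it fell. Alternative first exons changed in 113 of 339 events, and the upstream first exon rose in 81 of them (71.7%; interval 62.4 to 79.8; exact binomial adjusted p = 1.18e-05), JMJD1C among them, while C8orf76 went the other way. The call rate of first exons did not stand apart (Fisher adjusted p = 0.144).

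Longer forms fell in the other classes. Extended tandem 3' UTRs fell in 28 of 29 changed events (exact binomial adjusted p = 4.47e-07), among them IGFBP7, SRSF6 and EIF2S1, with PDXDC1 as the exception, at 0.23 in cytoplasm and 0.60 in polyribosomes. Of the 29, 6 lie on another strand or chromosome than the named gene. In this class 314059 reads fitted only the extended form and 0 only the shorter. Psi here thus compares coverage of the extension with that of the shared part, and a coverage bias was not tested. Retained introns fell in 32 of 37 events (adjusted p = 1.98e-05) and, with 1 event per gene, in 19 of 24. The falls include 3 overlapping forms of 1 intron of EIF4A1, and the rises were in COG1, NXF1, PTK7, RBM25 and SLC25A3. The longer form fell in 18 of 21 changed 5' splice site events (adjusted p = 0.00199), with CCNL2, FANCA and MED12 rising, and in 19 of 23 changed 3' splice site events (adjusted p = 0.00297), with KRT8, UBA1, UNC45A and WDR6 rising. Skipped exons were included less in polyribosomes in 68 of 103 changed events (66.0%; adjusted p = 0.00199), for example in GABPA, EMC1 and NDUFV3. Of the coding ones, 45 of 68 fell, against 15 of 25 in 5' UTRs and 8 of 10 in 3' UTRs, and these shares were not tested against each other. Mutually exclusive exons changed in 5 events, of EEF1D, IRF3, SNRPD2 and WDR6, with 2 higher and 3 lower. Over the 5 classes with a longer and a shorter form, the longer fell in 165 of 213 events (77.5%; interval 71.3 to 82.9) and, with 1 event per gene, in 123 of 160. Call rates were below those of the other classes for skipped exons (27.6%), 5' splice sites (20.4%), 3' splice sites (14.6%) and tandem UTRs (22.3%), with Fisher adjusted p between 5.98e-10 and 4.45e-04, and not for retained introns (47.4%; 0.0725) or mutually exclusive exons (23.8%; 0.259).

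**Figure D3:**
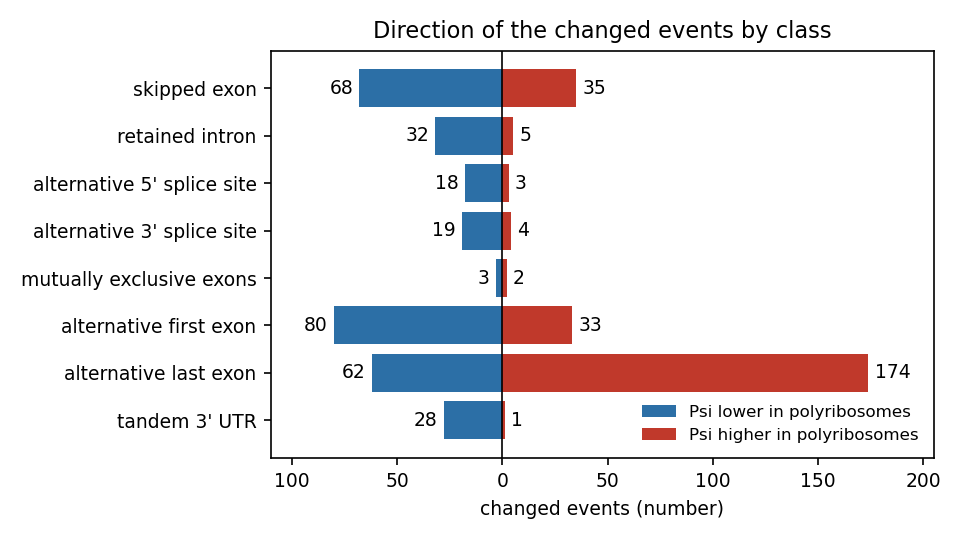
Number of changed events per class (x axis), with blue bars to the left for Psi lower in polyribosomes and red bars to the right for Psi higher. Last exons point to the right, with 174 higher and 62 lower, and skipped exons, retained introns, splice sites, first exons and tandem UTRs to the left.

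The series title concerns minor isoforms, so the isoform below 0.5 in cytoplasm was followed. It rose in polyribosomes in 345 of 563 changed events (61.3%; interval 57.1 to 65.3), such as BOD1L1, WDR6, FANCA and RBBP6, where a scarce form came to predominate, and fell in 218, such as TRA2A and SRSF5. Permuted signs gave a mean of 49.1% (p = 1e-05, the smallest that 100000 permutations can give). The permutation lets every event move either way, although a scarce isoform has less room to fall than to rise. Its p-value therefore cannot separate a preference for minor isoforms from this limit. In the rising events the median Psi of the minor isoform was 0.24 in cytoplasm and 0.585 in polyribosomes, and in 228 of the 345 it became the major one. A minor isoform named by cytoplasm cannot cross 0.5 by falling, so every crossing counts as a rise by this naming. By class the share was 74.5% for skipped exons, 65.8% for last exons, 57.1% for first exons, 56.5% and 52.4% for 3' and 5' splice sites, 3 of 5 for mutually exclusive exons, 44.8% for tandem UTRs and 29.7% for retained introns. The direction depends on which fraction names the minor isoform: named by the mean of both it rose in 42.4% (interval 38.3 to 46.6), and named by polyribosomes in 20.1%, that is, it was higher in cytoplasm in 79.9%. It also depends on the events taken, with 49.0% of 259 events whose minor isoform was at 0.3 or more (36.1% of the 166 with a difference of at most 0.3, a limit that took out 67 rises and 26 falls), 46.4% of 929 events not called, and 54.5% (interval 47.5 to 61.3) of 213 with at least 200 reads in each library.

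Skipped exons with a length that is a multiple of 3, such as the 1095-base exon of NDUFV3, were set against the others, such as the 292-base exon of EMC1. The median Psi difference was -0.015 in 152 exons of the first kind (quartiles -0.0663 and 0.0312) and -0.02 in 221 of the second (quartiles -0.115 and 0.05). The difference of the medians, 0.005, did not pass a permutation test (p = 0.763), nor did that of the 33 and 70 changed exons (0.0775; p = 0.222). Among coding exons, 112 and 138 of them, the difference was -0.01 (permutation p = 0.705).

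Among translation factors, 13 of 17 tested events differed, 3 higher and 10 lower, in all 6 genes with a tested event (Fisher adjusted p = 0.0181), and 13 when adjusted over the list alone. With 1 event per gene 5 differed and the list did not stand apart (adjusted p = 0.173). EEF1D, a subunit of the exchange factor for eEF1A, accounts for 6 of the 13, and several of these overlap: a 5' UTR splice site form on chromosome 8 from 144674817 to 144679845 fell from 0.935 ± 0.0212 to 0.435 ± 0.0778 (SD, n = 2; adjusted p = 5.12e-10), and skipped exons in the same UTR fell by 0.435 and 0.415. Overlapping forms of a retained intron of the helicase EIF4A1, between 7481145 and 7481562 on chromosome 17, had Psi differences of -0.210 and -0.195 (adjusted p = 0.00734 and 0.0123, and 0.0516 and 0.0757 without the block). Another form of this intron, outside the naming rule, had a difference of -0.165 (adjusted p = 1.04e-05). The extended 3' UTR of EIF2S1, a subunit of the factor that brings the initiator tRNA, went from 0.365 ± 0.0212 to 0.165 ± 0.0354 (SD, n = 2). The extended UTR of EIF1AX went from 0.530 ± 0.0141 to 0.360 ± 0.0707, with an adjusted p of 0.0419 that was 0.145 without the block. An EEF1D event of mutually exclusive exons rose by 0.180, with an adjusted p of 0.0338 that was 0.132 without the block.

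Among SR proteins, which regulate splicing, 6 of 8 tested events differed, 1 higher and 5 lower, and 6 when adjusted over the list alone, without standing apart from other genes (Fisher adjusted p = 0.125). The extended 3' UTR of SRSF6, on chromosome 20 from 42090417 to 42092245, fell from 0.955 ± 0.0212 to 0.695 ± 0.00707, and a longer 5' splice site form of TRA2A, between 23561326 and 23562051 on chromosome 7, from 0.225 ± 0.0495 to 0.055 ± 0.00707 (SD, n = 2; adjusted p = 1.23e-07 and 3.95e-07). PNISR moved both ways: its upstream last exon rose by 0.410 and a 5' UTR splice site form had a difference of -0.150. A 3' splice site form of SRSF5 had a difference of -0.140 with an adjusted p of 0.0241, which was 0.121 without the block. The 8 events of 6 ribosomal protein genes, RPL3, RPL9, RPL13A, RPL26, RPL41 and RPLP0, gave 0 calls in limma (Fisher adjusted p = 0.0963), 0 when adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by the Bayes factor rule, against 5 in the read-based Cochran-Mantel-Haenszel test, which covers counting error only.

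Chromatin regulators differed in 19 of 31 events, 6 higher and 13 lower (Fisher adjusted p = 0.0484; 21 when adjusted over the list alone), including first exons of BAZ2B and CHD2 and last exons of SUV420H1, a histone methyltransferase, and ARID4B; with 1 event per gene 9 differed (adjusted p = 0.315). The hnRNPs and splicing regulators differed in 10 of 16 events, 4 higher and 6 lower (adjusted p = 0.103; 11 when adjusted over the list alone), with exons of the cold-inducible RBM3 (-0.440) and CIRBP (-0.255) lower in polyribosomes and 5 changed events of HNRNPR going both ways. By the Bayes factor rule this list had 12 changed events (adjusted p = 0.0109). Ubiquitin and proteasome genes differed in 10 of 15 events, 7 higher and 3 lower (adjusted p = 0.0963; 10 over the list alone), with upstream last exons of USP48 and USP15 rising by 0.420 and 0.365. Core spliceosome genes differed in 5 of 8 (adjusted p = 0.251; 5 over the list alone), among them SNRPD2 and SF3B3. By the annotation at hand, of another build, the changed events named for PRPF4B and RBM8A in this list lie on another strand than the gene. The same holds for a rising first exon event named for PSMG4 in the ubiquitin and proteasome list. Those of PRPF4B and PSMG4 span 28759878 and 28500028 bases, so these gene names are uncertain.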

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

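The authors' deposited table of changed events lists 204 events outside the replicate tables, and 24 of them have Bayes factors of at least 5 in both control replicates, which is a signal in data that the comparisons above do not use. All 24 differences in the authors' deposited table have the same sign in both replicates, and in all 24 the size was at most 0.1 in at least 1 replicate. They include a retained intron of SRSF5 (-0.1 and -0.16) and a last exon of SRSF10 (-0.1 and -0.09), both SR proteins, and upstream last exons of CSNK2B and DIDO1, by the event coordinates in the authors' deposited table.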

How the results depend on the processing

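The alternatives with random spreading of Psi, 1 event per gene (outside the gene lists), at least 200 reads, a minor isoform at 0.3 or more with and without a limit on the difference, naming by polyribosomes, uncalled events, authors' marks, coding skipped exons, and strand and span were chosen after seeing the data. Of 567 changed events, 483 were called with no replicate block, all among the 567; the other fits with all libraries gave 487 to 568, the threshold of 0.1 gave 603 and the read-based test 830. Without 1 library and no block limma called 0 events each time, for the rounding given in the report. With Psi spread at random it called 305 without cytoplasm 1, 382 without polyribosome 1, 368 without cytoplasm 2 and 278 without polyribosome 2. Taking 1 event per gene gave 340 of 1114, against 567 of 1533, so fewer events were tested and a smaller share of them was called. Restricted to events on the strand of the named gene that span at most 1 Mb, 532 were called. A Psi difference of at least 0.2 left 312 events past the Bayes factor rule. The minor isoform rose in 60.5 to 71.7% under 6 alternatives, and the direction turned with naming by the mean of both fractions (42.4%), naming by polyribosomes (20.1%), uncalled events (46.4%), and a minor isoform at 0.3 or more with a difference of at most 0.3 (36.1%), a limit that took out more rises than falls. Without that limit it was 49.0%, and with at least 200 reads 54.5%, neither above 50% by its interval, and the cause was not tested. Class directions kept their side under each alternative tried, except for ties of 2 and 2 mutually exclusive events by the Bayes factor rule and with 1 event per gene. Of the gene lists, 2 passed, 3 by the Bayes factor rule and 0 with 1 event per gene, where fewer events were tested. The correlation between replicates was 0.94 at a width of at most 0.2, 0.96 in events marked different and -0.12 in those marked not different; the selection sets equal signs in the former, and otherwise the cause was not tested. The frame comparison passed its test under no alternative. Of 352 refits of 38 named events with all libraries, 338 kept the call, 14 lost it, in 5 events, and 0 changed direction; 5 were lost with no block. Small differences are often missed: 23.9% of simulated changes of 1 on the logit scale were recovered. The simulation did not vary depth, so the part played by the polyribosome medians of 101 and 98 reads was not tested.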

Other observations

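Outside the lists already described, the mTOR, PI3K and MAPK list had 2 changed events among 4, both upstream last exons of TSC1, a brake on mTOR signalling, with rises of 0.340 and 0.190 (Fisher adjusted p of the list 0.818). Both events of GAS5, a noncoding host of small nucleolar RNAs in the list of nuclear-retained RNAs, fell, with Psi differences of -0.340 and -0.295 (list adjusted p = 0.251). At least 155 reads fitted each event in every library of these cytosolic fractions, so the list's name does not describe the GAS5 RNA sequenced here. Genes of oxidative phosphorylation changed in 2 of 8 events, with exons of NDUFV3 and NDUFS1, both subunits of complex I, at mean differences of -0.535 and -0.360 (list adjusted p = 0.848). Cell cycle and mitosis genes changed in 4 of 15, all higher, in SMC1A, CCNL2, CDC23 and CEP78 (list adjusted p = 0.818). Cytoskeleton genes changed in 4 of 11, in DNM2, CALD1 and CFL2, and membrane traffic genes in 4 of 12, in GOLGA4, SNX5 and SEC22C (adjusted p = 1 for each). Adjusted over the list alone, the calls of these 6 lists numbered 2, 2, 2, 3, 4 and 4, and 0 events of nonsense-mediated decay factors could be tested.

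In the authors' deposited table, 108 of the 558 changed events it shares carry the label of rapamycin sensitivity. The label was on 31 of 102 skipped exons in the authors' deposited table (30.4%; Fisher adjusted p = 0.0264 over 8 classes), against 7 of 21 5' splice sites (33.3%; adjusted p = 0.305), 6 of 22 3' splice sites (27.3%), 37 of 235 last exons (15.7%) and 15 of 109 first exons (13.8%), none of which passed. The libraries behind the label were not analysed here.

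Chosen after results were seen were the tests of retained introns, of the cytoplasmic level of the upstream exon and of the longer form, of longer forms outside retained introns, of extended UTRs and of intervals past 0.5, and the wording of the noise explanation, which was narrowed. The tests with at least 200 reads and with room for both directions were added after the files were seen, the latter without its limit after its result, and the remaining predictions were written with the files at hand but before their results. The first pattern is the rise of the minor isoform in most changed events. A pull of shallow polyribosome libraries toward 0.5 is argued against for 114 of the 345 rises (33.0%, interval 28.1 to 38.3), RBBP6 among them. These have 95% intervals past 0.5 in both polyribosome libraries. The minor isoform became the major one in 228 rises, so the intervals do not cover all of those. For the rises outside the 114 a pull cannot be told apart from a real rise, with 54.5% (47.5 to 61.3) of 213 changed events with at least 200 reads in each library. Naming the minor isoform in one replicate and reading the direction in the other gave 62.0% and 61.0%, but all 567 changed events have the same sign in both replicates, so measurement noise stays open. That a scarce isoform has more room to rise stays open too. This explanation predicts no excess of rises where both directions have room, and none was seen there. The share was 36.1% of 166 events with a minor isoform at 0.3 or more and a difference of at most 0.3. That limit took out 67 rises and 26 falls, and without it the share was 49.0% (42.8 to 55.3).

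The second pattern is the rise of the upstream last exon, as in RBBP6 and CNTLN. Unequal lengths with a different fall of coverage toward the 3' end are argued against as the whole cause by 69.1% (interval 56.7 to 79.8) among 68 events whose regions differ in length by less than 1.5 times, although the share was 85.0% of 147 events with a shorter upstream region and 51.9% of 81 with a longer one, so length moves with it. Unspliced RNA in the polyribosome fraction would bring introns along, but 13.5% of 37 changed retained introns rose (4.54 to 28.8). A drift of Psi toward 0.5 is argued against for 38 of 124 rising upstream exons below 0.5 in cytoplasm (30.6%; 22.7 to 39.6), with 95% intervals past 0.5 in both polyribosome libraries, and stays open for the rest, since 61.0% of 77 events with an upstream exon above 0.5 rose (49.2 to 72.0), while 53 of 72 with at least 200 reads in each library did (73.6%). A preference of polyribosomes for mRNAs that end early is a hypothesis that these data may hold but do not settle.

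The third pattern is the fall of the longer form, as in IGFBP7, MOV10 and EIF4A1. A drift toward 0.5 is argued against as the whole cause, because 67.2% (interval 57.9 to 75.7) of 116 events with a longer form below 0.5 also fell, away from 0.5. It stays open for skipped exons, where the minor isoform rose in 76 of 102 changed events (74.5%), against 29.7% of retained introns and 44.8% of tandem UTRs. A few genes with many events do not carry it, with 76.9% (69.6 to 83.2) at 1 event per gene. Incompletely spliced RNA in the cytoplasmic extract is argued against for extended 3' UTRs, whose forms do not differ by splicing and of which 96.6% (82.2 to 99.9) of 29 fell, but it stays open for the other classes, since it carries skipped exons and splice site sequence too and 75.6% (68.5 to 81.7) fell outside retained introns. A lower association of longer forms with polyribosomes is a candidate explanation, found and tested on the same data, and biases of coverage along the transcript were not tested for these classes.

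A hypothesis written before its test held that first exons with an annotated upstream open reading frame would fall. They fell in 22.7% of 44 changed events in 30 genes (interval 11.5 to 37.8), the opposite of the prediction. In 36 of these the element lay on the upstream first exon, which rose in most events anyway, and in the 8 with it on the downstream exon 5 fell, so place and element were not separated. The elements are the authors' annotation, which is the same in both replicate tables for every event marked different and in 932 of those marked not different.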
